A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

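RNA was sequenced from 6 yeast cultures, 3 of a WT strain and 3 of a strain with the R256C substitution in actin. Per the labels' protocols, cells were collected in early exponential growth in rich medium, RNA was extracted after enzymatic lysis of the wall, and libraries were made with a stranded mRNA kit that selects poly(A) tails with oligo(dT) beads. The deposited table holds whole-number counts of reads per gene, not normalized, for the 6 libraries. The submitters' processing notes name TopHat, HTSeq and DESeq and the genome build R64, with no versions; the settings of the alignment and counting, strand among them, are not given in the sources used here. Such counts leave out reads placed at several loci, so genes with near-identical copies are counted only where their sequences differ.

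The table has 7131 rows, of which 7126 are genes and 5 are the counter's summary rows, which name no gene and stayed out of library sizes and tests. Reads outside any annotated gene were 3.60 ± 0.399% of uniquely placed reads in WT and 4.03 ± 0.0439% in R256C (SD, n = 3 each). Ambiguous reads were 7.68 ± 0.392% and 7.57 ± 0.125%. The counter's row for reads placed at several loci held 54.5 ± 2.11% and 56.2 ± 0.923% of the table's total. Whether that row holds such a read once or once per alignment is not given, so the share of reads may be lower. The libraries differed in these shares with p = 0.1, 0.8 and 0.3 by two-sided exact permutation tests, in which 0.1 is the smallest value possible. The other summary rows, for reads too low in quality or not aligned, held 0 in every library. Use of strand was checked from the data: 8 coding genes lie wholly inside a counted gene of the other strand, and all 8 had 0 reads in every library, as counting without strand would give. If strand was not used, reads of overlapping genes and of antisense RNAs could not be told apart. The check rests on these 8 genes alone.

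Gene identifiers were matched by locus tag to the R64 reference annotation, which gave coordinates and symbols for 6048 of the gene rows and none for 1078. Every column of per-library values belonged to a library of the series, and 0 were left over. Depth ranged from 8967232 to 16905818 reads in genes, and 327 gene rows had no count in any library. Replicates were compared before averaging: every pair of libraries differed beyond sampling noise (lowest chi-square per degree of freedom 7.15), so no library was counted a second time.

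Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (6337 genes), scaled by TMM factors, and tested with the quasi-likelihood F test (glmQLFit and glmQLFTest) with genotype as the only term and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and a further count required at least a 2-fold change. SE values are the log2 fold change divided by the root of the F statistic. CPM of single genes use TMM-scaled library sizes, and shares of RNA classes use plain totals. The common biological coefficient of variation was 0.133, and the median log2 fold change of all tested genes was -0.012. Intervals and tests rest on 3 cultures per strain, and limits set by a count of 0 (3 counts per library) cover counting error only.

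Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 3, a preset correlation of 0.01 and adjustment over the 49 lists with at least 3 tested members. The 50 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named ACT1; the 12 genes with the largest rise and the 12 with the largest fall among genes that passed, with a mean of at least 10 CPM and with all libraries of one strain above those of the other; up to 4 members with the smallest p of each list called or described; and all members of the lists on mating type, markers, the ACT1 neighbourhood and histones. Other genes were named after their values had been seen. The values of some members of these lists are not reported here.

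The scripts were tested on simulated data made from the means and library sizes of these libraries, with 6337 genes of which 200 were changed. Of the genes changed by 1.5-fold, 2-fold and 4-fold, 55.2%, 91.0% and 97.0% were recovered, and 15 of 177 genes called were unchanged. The adjusted threshold depends on the share of genes changed, so these rates hold for a simulation with 200 changed genes. A simulated list of 30 genes shifted by 0.5 on the log2 scale was called, and 0 of 49 unshifted lists were. The simulated genes varied independently of each other. The simulation therefore says nothing on false calls of lists whose members vary together, and the estimated correlation of ribosomal protein genes was 0.907. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals alone, no filter, a filter at 10 CPM in 3 libraries, leaving out each library, and the replicate number as a block, alone or with offsets for GC content or gene length. For lists, an estimated correlation, fry and fgsea 1.28.0 were also run. Chosen after seeing the data were the offsets without a block and a fit of protein-coding genes alone. GC content and length were known for 91.7% of the tested genes.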

Results

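Poly(A)-selected RNA was sequenced from 2 strains of the budding yeast Saccharomyces cerevisiae, labelled as the S288C background: a wild-type strain (WT) and a strain whose actin carries the R256C substitution, in which arginine is replaced by cysteine. The series sets this change in the context of a modified actin arginine and of transcription, and notes that the corresponding substitution in a human actin is a disease variant. The comparison of R256C with WT therefore asks which genes and gene sets differ in mRNA level between the strain with this substitution and WT. Growth rates and independent isolates of each genotype are not given in the sources used here. Other differences between the strains cannot be told apart from the substitution. Each strain was represented by 3 libraries, described in the labels as biological replicates, from cultures in rich medium at 30 °C harvested during early exponential growth at an optical density of 0.9. The reads counted in genes were 12476645, 16905818 and 10750023 in WT replicates 1, 2 and 3, and 11935735, 11165090 and 8967232 in R256C replicates 1, 2 and 3.

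ACT1 (YFL039C), the only conventional actin gene of this yeast and the gene that carries the substitution, was measured first in every sample. It lies on chromosome VI at 53260 to 54696 on the minus strand (R64), with coding exon 1 at 54687 to 54696, an intron of 309 bp at 54378 to 54686 and coding exon 2 at 53260 to 54377. The codon of this arginine in the 375-residue protein lies in exon 2 at 53620 to 53622 and reads AGA (arginine) in the reference, within the coding sequence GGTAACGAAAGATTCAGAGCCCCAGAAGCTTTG (53605 to 53637, peptide GNERFRAPEAL). ACT1 mRNA was at 1512, 2094 and 1608 CPM (counts scaled to library size) in WT replicates 1, 2 and 3, and at 1354, 1373 and 1404 CPM in R256C replicates 1, 2 and 3. The means were 1738 ± 312 CPM in WT and 1377 ± 25.2 CPM in R256C (SD, n = 3 each). The log2 fold change was -0.34 (SE 0.16) and did not pass edgeR's quasi-likelihood test (adjusted p = 0.124). DESeq2 gave -0.35 with an adjusted p of 0.0471. Without WT replicate 2, the WT library highest in ACT1, edgeR gave -0.18 (adjusted p = 0.0885). A point substitution need not alter the mRNA level, so ACT1 expression did not check the genotype labels, and gene counts do not show the base at the codon.

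The transcriptome of the R256C strain differed from WT in both directions over a large share of the genes. Of 6337 genes tested, 1345 rose and 1358 fell in R256C at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg), which is 42.7% of those tested. Of these, 365 rose and 179 fell by at least 2-fold. In a fit of protein-coding genes alone, 255 rose and 158 fell by as much, so a part of the large rises was in other rows. With a filter at 10 CPM, 232 rose by at least 2-fold. In 54.9% of the tested genes the 3 libraries of one strain lay entirely above those of the other, where chance gives 10%.

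The first principal component held 70.2% of the variance and separated the strains, and the second (18.6%) separated the WT libraries from each other. Correlations of log2 CPM ranged from 0.993 to 0.994 within R256C, from 0.977 to 0.993 within WT and from 0.957 to 0.964 between strains. WT replicate 2 lay apart from the other WT libraries: without it 1875 genes rose and 1884 fell, and 2671 of the 2703 genes called with all 6 libraries were called in the same direction. The counts were lower without WT replicate 3 (876 rose and 861 fell), and the count of genes that fell was 858 without R256C replicate 2 and 822 without R256C replicate 3. Scaling by library totals alone gave 1639 genes higher and 886 lower, so that 64.9% of the calls were higher instead of 49.8%.

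**Figure D1:**
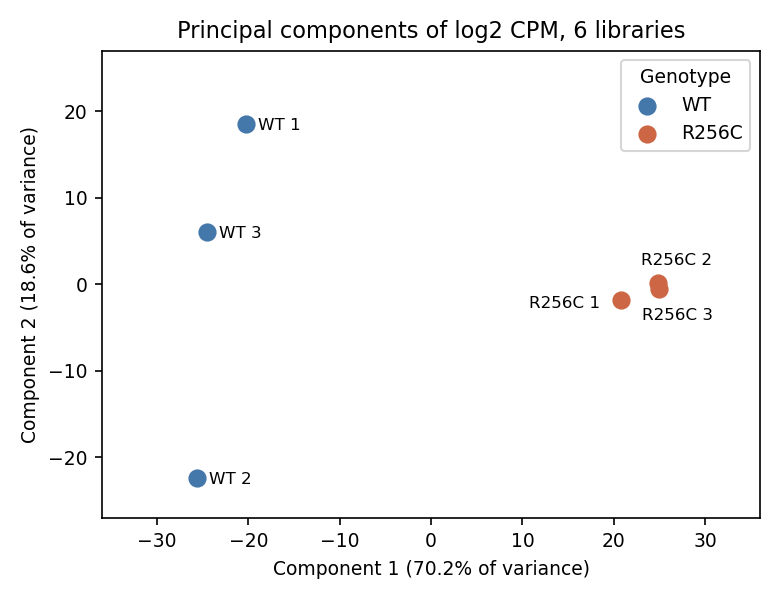
Principal components of log2 CPM over all tested genes, with one point per library coloured by strain; the axes give component scores and the share of variance. The strains separate along component 1 (70.2%), and WT replicate 2 lies at -22.4 on component 2, where WT replicates 1 and 3 lie at 18.6 and 6.05.

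Among the 12 genes with the largest rise, FRM2 (YCL026C-A, chromosome III, 74704 to 75285), a gene of the nitroreductase family, rose from 6.18 ± 1.06 to 61.0 ± 10.1 CPM (SD, n = 3 each; log2 fold change 3.30, SE 0.17, edgeR adjusted p = 1.6e-05). HEM13 (YDR044W, chromosome IV, 546642 to 547628), which encodes the oxygen-requiring coproporphyrinogen oxidase of heme synthesis, rose 8.23-fold, from 84.8 ± 25.4 to 699 ± 19.2 CPM (log2 fold change 3.04, SE 0.20, adjusted p = 3.1e-05). HAP4 (YKL109W, chromosome XI, 232227 to 233891), the activating subunit of the complex that switches on respiratory genes, rose 6.93-fold, from 107 ± 15.6 to 741 ± 70.7 CPM (log2 fold change 2.79, SE 0.15, adjusted p = 1.6e-05). The transcription factor genes STP4 (log2 fold change 2.85), GAT2 (2.83) and MGA1 (2.61) also rose, as did FMP48 (7.99-fold), which encodes a putative kinase, and ECM13 (2.59), a gene of unknown function. The transporter genes in this set were MAL11 (2.77) for maltose and HXT4 (2.64) and HXT6 (2.59) for hexoses. IZH4 (YOL101C), a membrane protein gene of zinc homeostasis, rose from 40.7 ± 0.798 to 245.9 ± 3.52 CPM (log2 fold change 2.59, SE 0.082, adjusted p = 2.3e-06). HXT6 has a near-identical relative, HXT7, so its separate value is uncertain.

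Among the 12 genes with the largest fall, PHO84 (YML123C, chromosome XIII, 24037 to 25800), the high-affinity phosphate transporter gene, fell from 2563 ± 1015 to 389 ± 20.3 CPM (SD, n = 3 each; log2 fold change -2.72, SE 0.29, edgeR adjusted p = 0.000236). PHO84 lies within an annotated antisense RNA, and reads of the pair could not be told apart if strand was not used. It had counts, unlike the 8 nested genes with 0 reads, so the check of strand does not settle its case. AHP1 (YLR109W, chromosome XII, 368781 to 369311), a thiol peroxidase gene, was among the most abundant transcripts and fell from 5427 ± 712 to 1249 ± 80.8 CPM (log2 fold change -2.12, SE 0.18, adjusted p = 8.0e-05). POL1 (YNL102W, chromosome XIV, 430087 to 434493), the catalytic subunit of DNA polymerase alpha, fell from 242 ± 32.5 to 59.8 ± 2.33 CPM (log2 fold change -2.02, SE 0.12, adjusted p = 1.9e-05). FIT2 (-2.51) and FIT3 (-2.05), cell wall mannoproteins that retain iron bound to siderophores, fell together, as did the acid phosphatase gene PHO12 (-2.30) and VTC3 (-1.81), which takes part in polyphosphate synthesis. The remaining genes were SPO19 (-2.13), known from spore formation, GCV2 (-1.98) of glycine cleavage, the carbonic anhydrase gene NCE103 (-1.96), RRT5 (-1.92) and YBL109W (-1.82), an identifier not matched to the annotation used here. Without WT replicate 2 the log2 fold change of PHO12 was -1.08, that of FIT2 -1.61 and that of VTC3 -1.21. The call of PHO12 (adjusted p = 0.0201) was lost with limma-voom (0.0610) and without R256C replicate 1 (0.0749), 2 (0.0842) or 3 (0.0599).

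**Figure D2:**
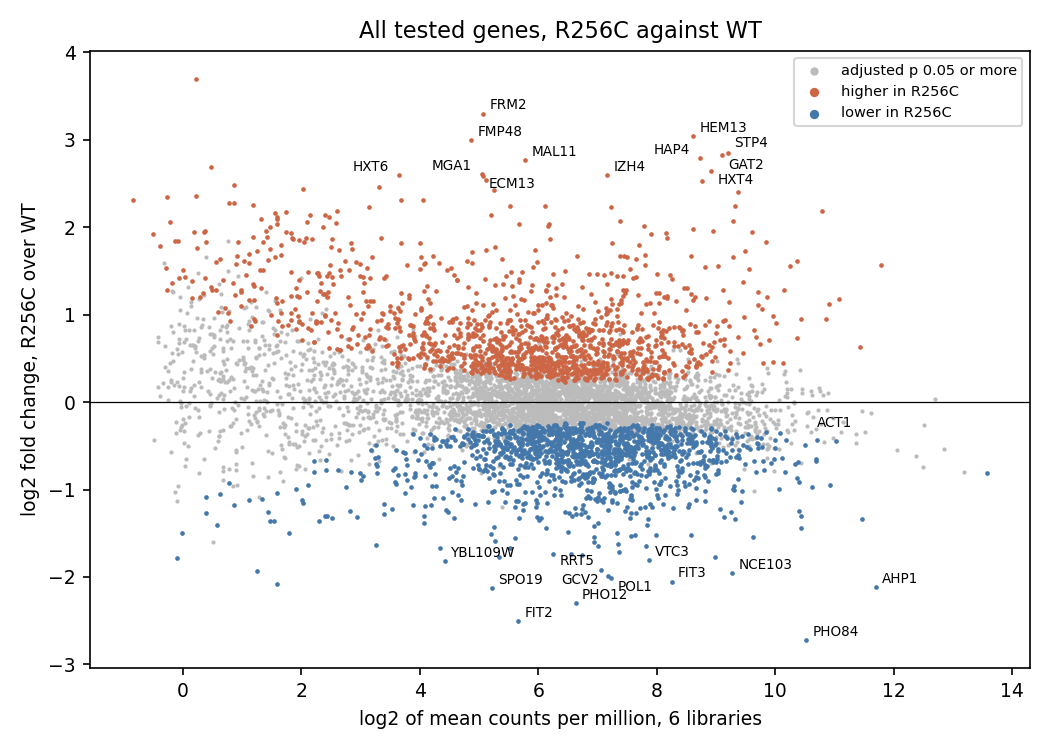
Log2 fold change of R256C over WT for each tested gene against the log2 of its mean CPM over 6 libraries; coloured points passed the test (1345 higher, 1358 lower), grey points did not, and ACT1 and the genes with the largest changes are named. FRM2 lies at 3.30 and PHO84 at -2.72.

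**Figure D3:**
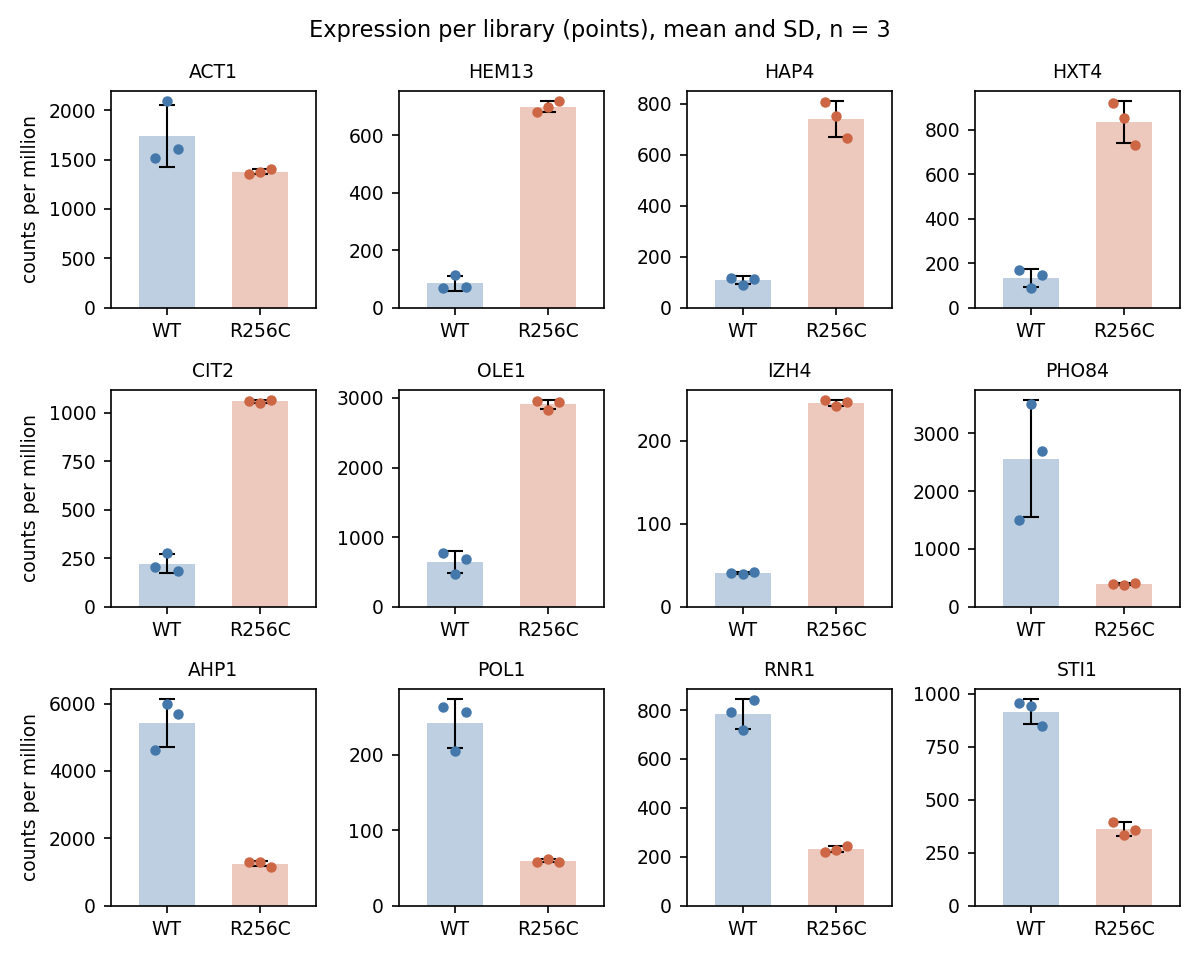
CPM per library (points) with the mean (bars, from 0) and SD (error bars) of 3 WT and 3 R256C libraries for 12 genes. The libraries of the strains do not overlap in any of the 12 panels. For HEM13, HAP4, HXT4, IZH4, PHO84, AHP1 and POL1 the rule that named them required this. ACT1, at means of 1738 and 1377 CPM, did not pass edgeR's test.

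A total of 50 lists of genes, fixed from textbook knowledge, were followed, of which 49 had members that could be tested, and 17 were called with limma's camera test (inter-gene correlation preset at 0.01; 8 higher and 9 lower in R256C). None of the 17 was called when the correlation was estimated from the data, where 5 lists had an unadjusted p under 0.05. For each list called, the adjusted p with an estimated correlation is given below, and the member counts come from edgeR's test of single genes. Some genes belong to several lists, CIT1, CIT2, SDH2, MDH2 and HXT6 among them, so the lists do not count as separate results. Members that moved against their list were named after their values had been seen, as were the members named for lists that were not called.

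Genes for sugar uptake and for carbon sources other than glucose were higher in R256C. Of 18 genes of hexose transport and its signalling, 11 rose, 1 fell and 6 did not pass (13 and 1 adjusted over the list alone, median log2 fold change 0.80, camera adjusted p = 0.00139, adjusted p = 0.626 with an estimated correlation). The low-affinity hexose transporter gene HXT3 rose from 1220 ± 101 to 2648 ± 290 CPM (SD, n = 3 each; log2 fold change 1.12, SE 0.15, edgeR adjusted p = 0.000801), and the glucose sensor gene SNF3 rose by 1.34 on the log2 scale. HXT4 and HXT6 rose as given above, HXT1 did not pass (0.20, adjusted p = 0.393), and RGT2, the other glucose sensor gene, fell (-0.36). Of 35 genes repressed by glucose, 19 rose and 2 fell (21 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.000136, adjusted p = 0.626 with an estimated correlation). MAL11 and MAL31 (2.24), for maltose transport, and MDH2 (1.56), a cytosolic malate dehydrogenase of gluconeogenesis, rose; the genes that fell were ALD6 (-0.95), for aldehyde dehydrogenase, and GAL10 (-0.38), for galactose use. In WT replicate 2 the median glucose-repressed gene was lower than in the other WT libraries (-0.31), as was the median hexose transport gene (-0.27).

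Genes of mitochondrial respiration and the tricarboxylic acid cycle were also higher. Of 12 genes of the retrograde pathway, which links the state of mitochondria to nuclear genes, 9 rose and none fell (9 and 0 adjusted over the list alone, median 0.68, camera adjusted p = 0.000447, adjusted p = 0.291 with an estimated correlation). CIT2, the peroxisomal citrate synthase and a standard readout of the pathway, rose from 222 ± 48.6 to 1057 ± 8.48 CPM (SD, n = 3 each; log2 fold change 2.25, SE 0.17, edgeR adjusted p = 4.7e-05). DLD3 (2.07), PDH1 (1.74) and CIT1 (1.67) rose as well. Of 25 genes of the tricarboxylic acid and glyoxylate cycles, 14 rose and 2 fell, LPD1 (-0.66) and FUM1 (-0.48), both enzymes of the former cycle (15 and 2 adjusted over the list alone, median 0.37, camera adjusted p = 0.00509, adjusted p = 0.499 with an estimated correlation). Of 41 nuclear genes of oxidative phosphorylation, 17 rose and 1 fell (17 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.00451, adjusted p = 0.711 with an estimated correlation). There were 9 to 20 rises in this list when one library was left out, and 8 to 15 in that of the tricarboxylic acid and glyoxylate cycles. SDH2 (1.13), RIP1 (0.93) and ATP1 (0.74) rose, and the gene that fell was CYC1 (-1.03), for the main form of cytochrome c. Of 36 genes of peroxisomes and fatty acid oxidation, 13 rose and 2 fell (13 and 2 adjusted over the list alone, median 0.21, camera adjusted p = 0.0238, adjusted p = 0.626 with an estimated correlation). FAA2 (1.33), FOX2 (0.94) and PEX7 (0.81) were among those that rose; FAA2 overlaps a neighbouring gene by 160 bp. Without WT replicate 2 the medians were 0.27 for oxidative phosphorylation and 0.19 for peroxisomes, near those of all 6 libraries, and the camera adjusted p was 0.0639 and 0.0759. The peroxisome median was 0.14 without R256C replicate 2. The p for peroxisomes was 0.0510 with a gene length offset.

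Lists of genes induced at low oxygen and of zinc homeostasis were higher in R256C. Of 25 genes of the hypoxic and cell wall mannoprotein families, 12 rose and 1 fell, the mannoprotein gene DAN4 (-0.81) (12 and 1 adjusted over the list alone, median 0.46, camera adjusted p = 0.00509, adjusted p = 0.291 with an estimated correlation). Besides HEM13, the fatty acid desaturase gene OLE1 rose from 640.2 ± 156 to 2908 ± 64.8 CPM (SD, n = 3 each; log2 fold change 2.18, SE 0.20, edgeR adjusted p = 0.000129), and the mannoprotein genes TIR2 (1.32) and PAU17 (1.04) rose. The PAU genes are close relatives, and reads could be shared among them. In WT replicate 2 this list lay above the other WT libraries, with a median of 0.37. Of 16 genes of zinc homeostasis, 9 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.61, camera adjusted p = 0.00422, adjusted p = 0.404 with an estimated correlation). IZH4, IZH2 (1.94), the zinc transporter gene ZRT1 (1.52) and FET4 (1.02), a low-affinity metal transporter gene, rose, and the genes that fell were RAD27 (-0.57), a DNA repair nuclease, and DPP1 (-0.24), a lipid phosphatase.

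Genes expressed at the start of the cell cycle, and those of spindle microtubules, were lower in R256C. Of 33 genes of the G1/S transition, 26 fell and 2 rose (26 and 3 adjusted over the list alone, median -0.75, camera adjusted p = 8.2e-09, adjusted p = 0.276 with an estimated correlation). RNR1, the large subunit of ribonucleotide reductase, fell from 784 ± 62.3 to 230.4 ± 12 CPM (SD, n = 3 each; log2 fold change -1.77, SE 0.12, edgeR adjusted p = 3.0e-05). POL1, the cohesin gene MCD1 (-1.60) and the DNA polymerase alpha gene POL12 (-1.23) also fell, while the cyclin genes CLN1 (0.33) and PCL1 (0.28) rose. Of 10 histone genes, most of them expressed in S phase, HHT2 rose (0.72, edgeR adjusted p = 0.0220) and the linker histone gene HHO1 fell (-0.65). The median was -0.057 (1 and 1 adjusted over the list alone, camera adjusted p = 0.958). The histone genes were higher in WT replicate 2 than in the other WT libraries (median 0.68), and without it 5 rose, 1 fell and the median was 0.22. The median was -0.21 without WT replicate 1 (1 rose, 2 fell) and -0.15 without WT replicate 3 (0 rose, 1 fell). HHT2 did not pass without WT replicate 3 (0.0952) or without R256C replicate 1 (0.0578), 2 (0.0860) or 3 (0.0650).

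Of 24 genes of the G2/M transition and of the M/G1 interval after it, 12 fell and 3 rose (15 and 3 adjusted over the list alone, median -0.27, camera adjusted p = 0.0484, adjusted p = 0.711 with an estimated correlation). SIC1 and PCL9 are among the M/G1 genes. MYO1 (-1.52), the myosin of the cytokinetic ring, BUD4 (-1.51), for bud site selection, and the polo kinase gene CDC5 (-0.84) fell. The genes that rose were CLB1, a mitotic cyclin, from 106 ± 1.12 to 283.5 ± 6.42 CPM (SD, n = 3 each; log2 fold change 1.42, SE 0.081, edgeR adjusted p = 1.9e-05), the cyclin-dependent kinase inhibitor SIC1 (0.54) and the cyclin PCL9 (0.46). Between 6 and 15 members fell when one library was left out. The list's call was lost without WT replicate 1 (median -0.24, adjusted p = 0.0580), WT replicate 3 (-0.25, 0.0620) or R256C replicate 3 (-0.26, 0.0611), with a filter at 10 CPM (0.0827), with a length offset (0.0856), over protein-coding genes alone (0.0706) and with fgsea (0.133). Of 21 tubulin and microtubule genes, 12 fell and 2 rose, the spindle positioning genes KAR9 (0.37) and KIP2 (0.25) (12 and 3 adjusted over the list alone, median -0.47, camera adjusted p = 0.00509, adjusted p = 0.291 with an estimated correlation). The spindle genes STU1 (-1.42) and STU2 (-1.08) and the kinesin genes KAR3 (-1.03) and KIP1 (-0.92) fell. Changes were unevenly related to gene length (Spearman rho -0.106 across genes, which are not independent replicates). Of 580 genes with a coding length of 2835 to 14733 bp, 263 fell and 40 rose (median -0.25), while of 580 genes of 1722 to 2103 bp, 105 fell and 162 rose.

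Chaperone and proteasome genes were lower. Of 23 heat shock chaperone genes, 17 fell and none rose (19 and 0 adjusted over the list alone, median -1.06, camera adjusted p = 2.3e-06, adjusted p = 0.499 with an estimated correlation). The co-chaperone gene STI1 fell from 915 ± 60.4 to 362 ± 31.2 CPM (SD, n = 3 each; log2 fold change -1.34, SE 0.12, edgeR adjusted p = 0.00012), and the mitochondrial chaperonin genes HSP60 (-1.25) and HSP10 (-1.06) and the sorting factor gene CUR1 (-1.15) fell. WT replicate 2 was lower in this list than the other WT libraries (median -0.42), and without it 22 members fell. Of 34 proteasome genes, 16 fell and 1 rose (16 and 1 adjusted over the list alone, median -0.32, camera adjusted p = 0.00157, adjusted p = 0.711 with an estimated correlation). The falls without one library ranged from 9 (R256C replicate 3) to 18 for proteasome genes and from 12 to 22 for chaperone genes. RPT1 (-0.80), PRE6 (-0.79), RPT4 (-0.55) and RPN12 (-0.46) fell, and the gene that rose was RPN4 (0.53), the transcription factor that activates proteasome genes.

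Lists of the translation machinery were called lower with all 6 libraries and were not called without WT replicate 2. Of 137 ribosomal protein genes, 35 fell and none rose (24 and 0 adjusted over the list alone, median -0.33, camera adjusted p = 7.9e-05, adjusted p = 0.833 with an estimated correlation). RPL22B (-1.34), RPL25 (-1.25), RPL6B (-1.16) and RPS9A (-1.07) fell; most of these genes are present as pairs of near-identical copies, so single values are uncertain. The median ribosomal protein gene was 0.68 higher on the log2 scale in WT replicate 2 than in the other WT libraries. Without that library 23 rose, 44 fell, the median was -0.046 and the call was lost (adjusted p = 0.187). The count that fell was 69 without WT replicate 1, 21 without WT replicate 3 or R256C replicate 1, 15 without R256C replicate 2 and 16 without R256C replicate 3. Of 104 ribosome biogenesis genes, 32 fell and 8 rose (30 and 8 adjusted over the list alone, median -0.19, camera adjusted p = 0.00532, adjusted p = 0.828 with an estimated correlation), including NOG2 (-0.96), DIP2 (-0.84), SSF1 (-0.69) and NOC4 (-0.68), of which NOG2 overlaps a small RNA gene. Without WT replicate 2 the median was little changed at -0.16, 47 fell, 18 rose and the adjusted p was 0.0614. Without R256C replicate 2 the median was -0.12 (0.0909) and 16 fell. Of 19 subunits of RNA polymerases I and III, 8 fell and 1 rose, RPC53 (0.57), a polymerase III subunit (8 and 1 adjusted over the list alone, median -0.21, camera adjusted p = 0.0480, adjusted p = 0.711 with an estimated correlation). RPA135 (-0.91), RPA43 (-0.86), RPO31 (-0.73) and RPC25 (-0.64) fell. The polymerase call was lost without WT replicate 2 (median -0.068, 0.188) or R256C replicate 2 (median -0.14, 0.102), with a filter at 10 CPM (0.0808), with the length offset (0.0795) and over protein-coding genes alone (0.0676).

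Genes of phosphate and iron acquisition held several of the largest falls. Of 20 genes of the phosphate regulon, 9 fell and 1 rose, PHM8 (0.73), for a nucleotide phosphatase (11 and 1 adjusted over the list alone, median -0.57, camera adjusted p = 0.0246, adjusted p = 0.762 with an estimated correlation). Besides PHO84 and VTC3, SPL2 (-1.77), a regulator of phosphate transport, and CTF19 (-1.14), a kinetochore gene next to VTC3 that overlaps another gene by 27 bp, fell. This list was 0.78 higher in WT replicate 2 than in the other WT libraries, and the call was lost without it (median -0.35, adjusted p = 0.0759; 11 fell, 4 rose). The count that fell was 12 without WT replicate 1, 5 without WT replicate 3 and 4 without any one R256C library. Of 29 iron regulon genes, 10 rose and 3 fell, FIT2, FIT3 and FIT1 (-1.67), all for iron-binding wall proteins (11 and 3 adjusted over the list alone, median 0.050, camera adjusted p = 0.403). This list too was higher in WT replicate 2 (median 0.40).

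**Figure D4:**
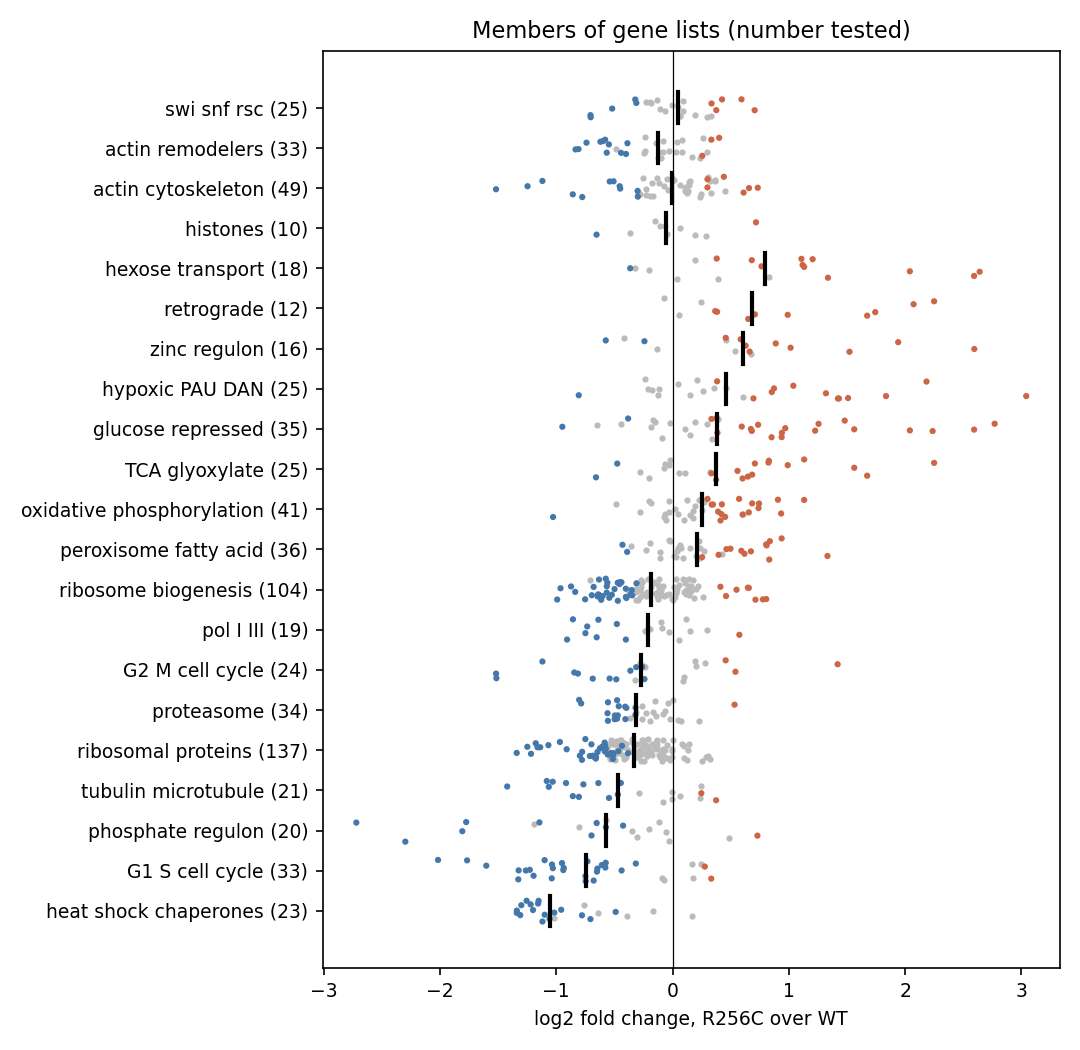
Log2 fold change of R256C over WT for the tested members of 21 gene lists (number tested in parentheses); red and blue points passed the test of single genes, grey points did not, and black bars are medians. Medians run from -1.06 for heat shock chaperones to 0.80 for hexose transport, and lie at -0.0069 for the actin cytoskeleton and 0.049 for the SWI/SNF and RSC remodelers.

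Lists of actin-binding proteins, of complexes that contain actin, of other chromatin remodelers and of the polymerase II machinery were not called with camera. Of 49 actin cytoskeleton genes, 11 fell and 6 rose (10 and 5 adjusted over the list alone, median -0.0069, camera adjusted p = 0.693). Without WT replicate 2, 17 fell and 17 rose, and without any other library 7 to 10 fell and 4 or 5 rose. The falls included the formin gene BNR1 (-1.25) and the myosin genes MYO1 and MYO2 (-0.86), and the rises included LAS17 (0.66), an activator of actin nucleation, and YSC84 (0.73). Of 33 subunits of the INO80, SWR1 and NuA4 chromatin complexes, in which nuclear actin is a subunit, 11 fell and 3 rose, IES1 (0.40), NHP10 (0.33) and IES6 (0.26) (13 and 3 adjusted over the list alone, median -0.12, camera adjusted p = 0.0928, fry adjusted p = 0.0185). With one library left out, 6 to 14 fell. ARP8 (-0.83), EAF1 (-0.81) and INO80 (-0.74) were the largest falls. Of 25 subunits of the SWI/SNF and RSC remodelers, 5 rose and 5 fell, in both counts (median 0.049, camera adjusted p = 0.963): RSC9, SNF11, SWP82, SNF6 and SNF12 rose, and STH1, SNF2, SNF5, RSC2 and SWI1 fell. Of 45 genes of RNA polymerase II, its general factors and Mediator, 13 fell, including RPO21 (-0.65), the largest polymerase II subunit, and 4 rose, MED4, SSN3, TFG2 and NUT1, in both counts (median -0.064, camera adjusted p = 0.261, fry adjusted p = 0.0149). The fry test asks whether the members move one way on balance, without comparing them with other genes, and is given here for lists that it called and camera did not.

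Lists of stress responses held changes both ways and were not called with camera. Of 51 general stress genes, 13 rose and 6 fell, in both counts (median 0.17, camera adjusted p = 0.202): TPS2 (1.95), for trehalose synthesis, rose, while the glycerol synthesis gene GPD1 (-1.44) and the small chaperone gene HSP26 (-1.42) fell. In WT replicate 2 the median general stress gene lay at -0.58 (log2) relative to the other WT libraries. Of 18 genes of trehalose and glycogen, 6 rose and 2 fell, UGP1 and GLG2, in both counts (camera adjusted p = 0.210). Of 29 cell wall integrity genes, 12 rose and 6 fell in both counts (median 0.28, camera adjusted p = 0.0768, fry 0.00658, fgsea 0.0128), with YPK2 (1.67) and SED1 (1.57) the highest and SWI4 (-1.33), for a G1/S transcription factor, the lowest. Of 21 genes of the unfolded protein response, 9 fell and 3 rose, DER1, EPS1 and HRD1, in both counts (camera adjusted p = 0.0810, fry 0.00137). Of 25 genes of the Yap1 oxidative response, 6 rose and 5 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.610), with AHP1, TRX2 (-0.90) and TRR1 (-0.70) among the falls. Of 20 DNA damage genes, 7 fell and 5 rose, RNR2, RNR3, RNR4, RFX1 and PHR1, in both counts (camera adjusted p = 0.644, fry 0.0174). Of 17 genes of the osmotic response, 4 rose (SKO1, CTT1, HOR7 and GCY1) and 4 fell (DAK1, GRE2, GRE3 and GPD1) in both counts (camera adjusted p = 0.963). Of 16 chaperonin and prefoldin genes, whose products fold actin and tubulin, 4 fell (PAC10, PLP2, CCT5 and YKE2) and GIM3 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.127).

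Among metabolic lists, 28 genes of sulfur and methionine metabolism gave 13 falls, led by the methionine synthase gene MET6 (-1.52), and 5 rises, MET8, SUL1, MET14, MET4 and STR2 (14 and 5 adjusted over the list alone, median -0.34, camera adjusted p = 0.0636, fry 0.00486, fgsea 0.0490). Of 65 genes of amino acid synthesis, 16 rose and 11 fell in both counts (camera adjusted p = 0.474). Of 28 ergosterol genes, 7 rose and 6 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.810). Of 20 genes of inositol and phospholipids, 5 rose (OPI1, ITR1, INO2, INO4 and FAS2) and 4 fell (CPT1, CHO2, EPT1 and PSD1) in both counts (camera adjusted p = 0.457, fry 0.0338). Of 21 glycolytic genes, 4 rose, HXK2 (0.95), PYK2, ENO1 and PDC5, and PDC1 (-0.82) fell (3 and 1 adjusted over the list alone, median -0.29, camera adjusted p = 0.929). The glycolytic genes were 0.46 higher in WT replicate 2, and without it 6 rose and 7 fell. Of 14 drug efflux genes, 5 rose (TPO1, ICT1, YGR035C, RSB1 and RTA1) and 4 fell (PDR1, PDR3, PDR5 and FLR1) in both counts (camera adjusted p = 0.929). Of 74 mitochondrial ribosome genes, 15 fell and 8 rose (13 and 4 adjusted over the list alone, camera adjusted p = 0.238). Of 11 housekeeping genes, TRS65 rose and none fell, in both counts (camera adjusted p = 0.588).

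Lists of differentiation were not called with camera either. Of 41 meiosis and sporulation genes, 13 rose and 4 fell, SPO19, SPO21, SPO75 and RED1, in both counts (median 0.30, camera adjusted p = 0.0693). Of 25 pheromone response genes, 8 fell and 2 rose, PRP39 and PRM3 (11 and 2 adjusted over the list alone, camera adjusted p = 0.180). Of 12 cell separation genes, 5 fell (DSE4, DSE1, CTS1, SCW11 and BUD9) and 3 rose (ASH1, AMN1 and PRY3) in both counts (camera adjusted p = 0.492). Of 10 flocculation and adhesion genes, 4 fell, FIG2, AGA1, FLO10 and FLO5, and none rose, in both counts (camera adjusted p = 0.202, fry 0.0183). Of 13 subtelomeric genes, COS10, COS111 and COS9 rose and YRF1-2 and COS6 fell, in both counts (camera adjusted p = 0.141, fry 0.0216, fgsea 0.0366); these belong to families of near-identical members. Of 13 haploid-specific genes, STE18, FAR1 and SST2 fell and RME1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.270, fry 0.00127).

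Several classes of RNA that lack long poly(A) tails took a larger share of the counts in each R256C library than in any WT library. Transfer RNA genes together took 363 ± 181 CPM of gene reads in WT and 1073 ± 339 in R256C (SD, n = 3 each), a ratio of 2.96. SCR1, the RNA of the signal recognition particle, took 1234 ± 409 and 2520 ± 458, and RPR1, the RNA of RNase P, took 367 ± 121 and 676 ± 126. Small nucleolar and nuclear RNAs named snR took 2195 ± 36.9 and 2775 ± 55.3, while the telomerase RNA TLC1 took 280.3 ± 7.24 in WT and 232 ± 2.58 in R256C. The 3 libraries of the strains did not overlap in any of these classes; each gave p = 0.1 in a two-sided exact permutation test, the smallest that 3 against 3 allows.

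Genes that mark mating type and laboratory genotype did not set the strains apart by type. None of the 7 MATa-specific genes passed (0 adjusted over the list alone, camera adjusted p = 0.958), and the pheromone receptor gene STE2 was at 773 CPM in WT and 779.7 CPM in R256C. Of 4 MATalpha-specific genes tested, MF(ALPHA)1 passed at levels near the floor (0.671 and 1.54 CPM; log2 fold change 1.19, edgeR adjusted p = 0.0268; 1 adjusted over the list alone, camera adjusted p = 0.238, fry 0.0295). That call was lost with DESeq2 (0.0559) and without WT replicate 1 or 3 or R256C replicate 1 or 2 (0.0630 to 0.0919). Of the marker genes, LEU2, URA3 and MET17 had 0 counts in all 6 libraries, which allows up to 0.177 CPM in the deepest library and 0.335 CPM in the shallowest. HIS3, TRP1, LYS2 and CAN1 did not pass, and ADE2 fell (-0.95, adjusted p = 0.00143), 1 of 5 marker genes tested in both counts (camera adjusted p = 0.403, fry 0.0354). Among 7 genes near ACT1, the beta-tubulin gene TUB2 (-0.86) and FRS2 (-0.72) fell, FET5 (0.40) and AGX1 (0.62) rose, and YPT1, YFL040W and RPO41 did not pass (2 and 2 adjusted over the list alone, camera adjusted p = 0.958). No member of the mitochondrial genome list had enough counts to be tested.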

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

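The tests of read depth and of abundant genes in WT replicate 2 were chosen before their results were seen; the tests on G1/S genes, on a common shift in that library and on RNAs without poly(A) tails were chosen after. Reads outside any annotated gene, which no comparison of the report uses, made up 4.03 ± 0.0439% of uniquely placed reads in R256C against 3.60 ± 0.399% in WT (SD, n = 3 each). This was singled out because each R256C library lay above every WT library. Such a separation fixes the two-sided exact permutation p at 0.1, the smallest it can give, so the test adds no support.

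WT replicate 2 stood apart from the other WT libraries, with more counts of ribosomal protein, histone and phosphate genes and fewer of general stress genes. Greater read depth is argued against, because thinning the library to the depth of WT replicate 3 left its distance on the second component at 1.02 of the value before. Removing the 12 genes that were among the 10 most abundant of any library left the distance at 0.998, which decides nothing, since so few of 6337 genes could hardly move this component. A shift common to all other genes, from scaling against abundant ones, is argued against by a difference of 1.26 between ribosomal protein and general stress genes. Without those 12 genes their medians relative to the other WT libraries were 0.68 and -0.58 on the log2 scale (SD over genes 0.221 and 0.486). A difference in growth stage, handling or library preparation of that culture may remain; no test here separates these, and the labels give no batch.

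The G1/S genes were lower in R256C, with a median of -0.75 (camera adjusted p = 8.2e-09, adjusted p = 0.276 with an estimated correlation). A trend with gene length is argued against, since the median was -0.79 after a length offset and 0 of 10000 random lists matched on length reached it (lowest -0.38). WT replicate 2 alone is argued against, since the median was -0.72 without it. A smaller share of cells between late G1 and S phase might lower the histone genes by a like amount, a premise that was not tested. Their median was -0.057 with an SD of 0.371 over genes, and it was -0.21 without WT replicate 1 and 0.22 without WT replicate 2. These genes varied together between libraries (estimated correlation 0.885), so that SD does not measure the spread between cultures. The values argue only against a fall of histone genes equal to that of G1/S genes. A change in transcription or stability of G1/S mRNAs in the mutant stays open as a hypothesis and was not tested further.

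Several RNAs without long poly(A) tails were higher in R256C, while the telomerase RNA TLC1 was lower (232 CPM of gene reads against 280.3). Among WT libraries the summed share of snR RNAs varied 1.03-fold while SCR1 varied 1.91-fold. For that summed share this argues against a common carry-over through poly(A) selection as the whole cause. Other measures varied more among WT libraries: NME1 1.19-fold, LSR1 1.25-fold and single snR genes by a median of 1.34-fold (69 genes other than snR6 and snR52). A carry-over that explains a part of the rise therefore stays open. For transfer RNA, SCR1 and RPR1, a change shared by RNA polymerase III transcripts was considered. snR6 and snR52, transcribed by that enzyme, both ordered the 6 libraries as SCR1 did (Spearman rho 1). The median rho was 0.314 for 69 other snR genes, of which 2 also had a rho of 1. LSR1, made by another polymerase, ordered the libraries as SCR1 did too. The ordering therefore does not single out polymerase III transcripts, and such a change stays possible but is not shown. A polymerase III change would not by itself raise RNAs made by other polymerases, yet LSR1 rose 1.38-fold and NME1 1.47-fold, which is left open. The snR class, in which snR6 and snR52 are included, rose 1.26-fold. Transfer RNA, SCR1 and RPR1 shares were correlated over the 6 libraries, as given among the other observations. Whether this lies in transcription, in RNA processing or in how short and structured RNAs enter the libraries stays open.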

How the results depend on the processing

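The offsets without a block and the fit of protein-coding genes alone were chosen after seeing the data. None of the called lists, nor of the 87 named genes that were called, changed direction under any alternative run, and 84 of these genes kept their call under each of the 18 settings that tested them; PHO12, HHT2 and MF(ALPHA)1 lost it under some. Leaving out one library gave 876 (without WT replicate 3) to 1875 genes higher and 822 (without R256C replicate 3) to 1884 lower, with 861 lower without WT replicate 3 and 858 without R256C replicate 2. Library totals alone gave 886 genes lower, against 1358 with TMM, because the median log2 fold change shifted from -0.012 to 0.087. A filter at 10 CPM left 232 genes at least 2-fold higher, against 365, because it removes weakly expressed genes. DESeq2 called 1384 genes higher and 1482 lower, and called ACT1 (-0.35, adjusted p = 0.0471; elsewhere 0.0617 to 0.271), for which the cause was not tested. With an estimated correlation camera called 0 lists higher and 0 lower (5 at an unadjusted p under 0.05; fgsea called 10 and 9), and the estimated correlations of the called lists reached 0.907. The directional fry test, which does not compare a list with other genes, called 14 lists lower and 12 higher. It did not call ribosomal proteins (0.255), ribosome biogenesis (0.141) or phosphate genes (0.126), and it called several lists that camera did not, among them the unfolded protein response (0.00137) and haploid-specific genes (0.00127). Both fry and fgsea called the lists of cell wall integrity, sulfur metabolism and subtelomeric genes, which camera did not. Leaving out one library gave 5 to 11 lists lower, with 5 without WT replicate 2, where ribosomal proteins, ribosome biogenesis, phosphate and polymerase I and III genes were no longer called. Of these, ribosome biogenesis kept most of its median (-0.19 and -0.16), while that of ribosomal proteins went from -0.33 to -0.046. Among lists not called, the median of histones went from -0.057 to 0.22 without that library and that of glycolysis from -0.29 to 0.011. The histone gene HTB2 went from -0.062 to 0.317 and then passed (adjusted p = 0.0116). Equal replicate numbers did not mark pairs: deviations from the group means correlated at -0.11, -0.068 and -0.069 between samples of the same number, so no sample correlated best with its own number. With the replicate number as a block, 1217 genes were higher and 1214 lower, the ACT1 log2 fold change was -0.32, MF(ALPHA)1 was the only named gene that lost its call, and the lists called remained 8 and 9. At 8967232 to 16905818 reads, the simulation recovered 55.2% of 1.5-fold changes. It changed 200 of 6337 genes, where 2703 were called in the data, and the adjusted threshold depends on that share. The 55.2% is therefore not the recovery rate of the real comparison, in which small differences may still be missed.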

Other observations

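The splits of the libraries were planned; the tests of chromosome ends and of chromosome copies were chosen after the data were seen, as were the comparison of polymerase III transcripts and the correlations within strains. The shares of transfer RNA, SCR1 and RPR1 rose and fell together over the 6 libraries. Transfer RNA shares correlated with SCR1 at r = 0.991 and with RPR1 at r = 0.987, and SCR1 with RPR1 at r = 0.997; each had a permutation p of 0.00139 and a Spearman rho of 1 (p = 0.00278), and Benjamini-Hochberg adjustment over these 3 relations left the values as they were. Without the 2 libraries farthest from the median of the first measure, r was 0.9987, 0.984 and 0.991. Part of this follows from the difference between the strains. With values centred by strain and orders permuted within both strains, r was 0.971, 0.957 and 0.998 (Spearman rho 0.943, 0.943 and 1). Each gave a permutation p of 0.0278, raw and adjusted over the 3 relations, the smallest value that 36 orders allow. Without the 2 libraries farthest from the median of the first centred measure, r was 0.995, 0.991 and 0.997. The RNA of RNase MRP, NME1, took 138 ± 11.9 CPM of gene reads in WT and 204 ± 2.79 in R256C, and the spliceosomal RNA LSR1 took 1164 ± 144 and 1602 ± 72.9 (SD, n = 3 each; two-sided exact permutation p = 0.1 each, the smallest possible).

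Reads from genes of the mitochondrial genome were few in both strains: 33, 16 and 17 in WT and 29, 25 and 16 in R256C. The large mitochondrial ribosomal RNA had 85, 77 and 63 reads in WT and 96, 77 and 61 in R256C, and the small one had 21, 19 and 13 against 15, 31 and 16. These values come from poly(A)-selected libraries and were not tested.

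Genes close to chromosome ends were higher in R256C as a set. Of 190 tested genes within 20 kb of an end, 60 rose and 22 fell, so that 31.6% rose, against 20.1% of the other genes. A hypothesis is that silencing near chromosome ends is weaker in the mutant. The median log2 fold change of these genes exceeded that of random sets matched on mean expression by 0.21, and 0 of 10000 random sets were as high. Leaving out one library gave differences of 0.14 to 0.29, which straddle the limit of 0.2 that had been set, and without R256C replicate 2 or 3 some random sets were as high (8 and 2 of 10000). The hypothesis therefore stays open. Genes near ends also include families of near-identical members, whose reads may be shared. Members of the lists described above were not set aside, so the excess may not be separate from those results.

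An additional copy of a chromosome would raise the median of its genes by about the ratio of copies. The highest median log2 fold change of a chromosome was 0.068, on chromosome VI, and the lowest was -0.087, on chromosome III, which argues against a gained chromosome in the R256C cultures as a whole.

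Splits of the 6 libraries into 3 and 3 were compared with the real one. With 10 splits the share that is as large can never be under 0.05. The real split gave 2703 genes and 544 genes at least 2-fold changed, and 1 of 10 splits, the real one, gave as many; the highest of the other splits gave 0 genes in both counts with edgeR, with 2 to 328 at an unadjusted p under 0.05. For the gene lists, 4 of 10 splits gave as many as the 17 of the real split, and the highest of the others gave 20. The other splits called 9 to 20 lists. Each of them sets 2 libraries of one strain and 1 of the other against the rest, so part of the genotype difference stays in them. In the gene tests the rest of that difference lies within the groups and widens their spread. The 0 genes of the other splits are therefore no measure of chance. The real median was larger in size than in every other split for 14 of the 17 lists; the exceptions were ribosomal proteins, phosphate genes and polymerase I and III subunits.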
